A study of Mus musculus with 12 samples.

How the data were processed

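The series holds RNA-seq of 12 mouse libraries in 4 groups of 3: embryonic fibroblasts (MEF), reprogramming cultures at day 4 (D4), reprogramming cultures at day 4 labelled with Dux overexpression (D4_DUX), and induced pluripotent stem cells (iPSC). Per the labels' protocols, the fibroblasts came from 13.5 dpc male homozygous 4F2A embryos, and culture used LIF and doxycycline at 2 μg/mL, a text shared by every sample. Per the labels, D4 carries the treatment OE-NC, the control of the overexpression, and D4_DUX the treatment OE-DUX, with overexpression for 48 h. Per the labels' protocols, polyadenylated RNA was selected, stranded libraries were made with 15 PCR cycles, and paired reads of 150 bp were sequenced on a NovaSeq 6000. Per the submitters' processing notes the genome build was mm10. The aligner, the counting tool and the gene annotation are not given in the sources used here, nor whether counting used the strand of the reads.

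The authors deposited one gene table in FPKM, counted fragments scaled by gene length and by the total of the library, with 1 column per library and 40384 Ensembl gene IDs. Of these, 40225 (99.6%) matched GENCODE M21, whose build GRCm38 is the mm10 build of the submitters' notes, and took their symbol, position and biotype from it. A symbol was shared by 169 of the IDs. The unit was checked on the values. The deposited FPKM values times the union exon length of M21 of low genes were steps of a constant per library. Within a tolerance of 0.01, 41.9 to 43.6% of low values were whole multiples of it and 70.3 to 71.9% were multiples of 0.5 of it. Fractional steps can occur where a shared fragment is divided between genes, which was not tested here. The step gave the depth, 22530000 to 28130000 counted fragments per library, and the recovered fragments of a gene, used for floors, for family sums and for 1 alternative. FPKM totals were 305025 to 316995 per library, and no scaling between libraries was seen. All columns were used. No pair of columns was identical (0 of 66), and libraries of a group correlated at Pearson r 0.9936 to 0.9966 on the log2 scale.

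Values were analysed as log2(FPKM + 1). Genes with FPKM of at least 1 in at least 3 of the 12 libraries were tested, 17114 genes. A limma model with 4 group means was fitted to all 12 libraries, with an empirical Bayes variance prior that follows mean expression, in R 4.3.3 with limma 3.58.1. The comparisons were D4_DUX against D4, D4 against MEF, and iPSC against MEF. A gene counted as higher or lower at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. Because 1 is added before the logarithm, log2 fold changes of genes with low FPKM are smaller than the ratio of their FPKM values. The libraries of a group were treated as independent. The labels do not say whether they are separate cultures. If they are not, the p-values and the chance share of genes without overlap do not cover differences between cultures. No replicate block was used, since no label pairs the replicate numbers.

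A set of 25 gene lists was fixed before the data were examined: 2-cell-stage genes, glycolysis and lactate, oxidative phosphorylation, the tricarboxylic acid cycle, serine and one-carbon metabolism, cholesterol synthesis, epithelial, mesenchymal, fibroblast matrix and pluripotency genes, the transgene factors, histone lactylation enzymes, BAF complex subunits, cell cycle, p53 target, stress, interferon response and immediate early genes, mitochondrially encoded genes, and markers of macrophages, endothelium, skeletal muscle, neural cells, endoderm and trophoblast. The list called histone lactylation enzymes holds writers, erasers and genes related to lactyl-CoA. The 21 lists with at least 5 tested members were tested with camera at a preset correlation of 0.01 between genes. Adjustment was over the lists of a comparison. Camera with the correlation estimated from the residuals, and fry, were run as alternatives. Member counts are given over all genes tested and adjusted over the list alone. The mitochondrially encoded genes, fixed as a sign of RNA quality, had 0 of 13 members in the table and gave no value.

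The position of a library between fibroblast and iPSC was its projection on the difference between the iPSC mean and the MEF mean, with the MEF mean at 0 and the iPSC mean at 1. D4 and D4_DUX positions were compared with an exact two-sided permutation test, which at 3 against 3 cannot go below 0.1. Spearman's rho compared both differences across genes, which are not independent replicates.

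The genes named were set by a rule fixed before the data were examined: Dux (Duxf3 in M21), Pou5f1, Sox2, Klf4, Myc, Smarca4, Ep300, Cdh1 and Ldha; the 8 genes at each end of the log2 fold change, among called genes with no overlap between the groups, a mean FPKM of at least 5 in the higher group and a symbol that is not a predicted-gene name; and, from each list, up to 4 members with the smallest adjusted p. Other genes are said where they appear to have been chosen after their values were seen. Floors are 3 fragments per library. Floors cover counting error only, since reads copied in PCR without molecular identifiers are not independent molecules.

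Alternatives fixed before the data were examined were pseudocounts of 0.1 and 0.5, no filter, a filter at FPKM 5, median-ratio scaling, rescaling to TPM (every library to the same total), quantile normalization, fitting only the groups compared, a replicate block, a variance prior without a trend, other gene sets for the position and rho, and leaving out each library in turn. Added after the data were seen were limma voom on the recovered fragments, protein-coding genes only, and the list tests under the other scalings. All 10 splits of the 6 libraries of each comparison were refitted. The chain was tested on simulated data with an assumed dispersion of 0.01 and 200 changed genes, so the shares recovered are not limits of the deposited data. For D4_DUX against D4 it recovered 37.3% of genes changed 1.5-fold, 70.1% at 2-fold and 84.8% at 4-fold, and called 4 of 14788 unchanged genes. Other tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.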

Results

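Polyadenylated RNA was sequenced from 12 libraries of mouse 4F2A cells, which carry doxycycline-inducible transgenes for the reprogramming factors Oct4 (Pou5f1), Sox2, Klf4 and Myc. The groups were MEF (embryonic fibroblasts), D4 (day 4 of reprogramming with the overexpression control), D4_DUX (day 4 with the label of Dux overexpression) and iPSC (induced pluripotent stem cells), with n = 3 libraries each. Depth was 22530000 to 28130000 counted fragments per library, and FPKM of at least 1 was reached by 14287 to 15834 genes. Group values are mean FPKM ± SD of n = 3 libraries, positions are in GRCm38, and log2 fold changes are on log2(FPKM + 1) with the SE of the limma fit. A signed number in parentheses after FPKM values, and the size after "rose by" or "fell by", is a log2 fold change.

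The series concerns Dux, a homeobox transcription factor of the 2-cell embryo, and links it to metabolism, histone lactylation and the change from mesenchymal to epithelial cells, with Brg1 (Smarca4) as a protein that binds lactylated histones. The annotated Dux gene, Duxf3 (ENSMUSG00000075046, chromosome 10, 58229979 to 58232675), did not carry the label's change. Duxf3 was listed at 0 FPKM in all 3 libraries labelled D4_DUX, at 0.00741, 0.00747 and 0 in D4, and at or below 0.0247 in MEF and iPSC. A floor of 3 fragments corresponds to 0.0395 to 0.0494 FPKM, so Duxf3 stayed below the floor in all 12 libraries. Differences under the floor cannot be read, and the counted fragments showed no overexpression of Duxf3 in the group labelled D4_DUX. The directions given for this group are therefore those of the libraries labelled D4_DUX. Known targets of Dux were nevertheless found in them at low levels. Fragments summed over Zscan4a to Zscan4f, genes of the 2-cell stage that share sequence, were 38.33, 24.98 and 20.28 in the 3 libraries labelled D4_DUX and 0 in each of the 3 D4 libraries. They were 0, 1 and 1.25 in MEF and 44.94, 97.68 and 160.25 in iPSC. Of 38 listed 2-cell-stage genes 35 were in the table, and 5 of these had at least 3 fragments in every library labelled D4_DUX and fewer in every D4 library, against 0 with the reverse, a count chosen after the values were seen. They were Zscan4b, Zscan4e and Zscan4f, which can share fragments, and Usp17ld and Usp17le, which belong to another family of similar genes. Only 2 members passed the filter for testing: Zfp750 fell (log2 fold change -0.50, adjusted p = 0.00057) and Nelfa had 0.07 (adjusted p = 0.249), the same 1 lower and 0 higher when adjusted over the list alone.

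The comparison of the libraries labelled D4_DUX with D4 addresses what Dux overexpression changed at day 4. Fibroblast matrix genes (16 of 26) and macrophage markers (14 of 16) were lower in the libraries labelled D4_DUX, with camera adjusted p = 6.05e-07 and 2.26e-11, and adjusted p = 0.546 and 0.0717 with an estimated correlation. The other lists that fell stood beside macrophage markers with a median log2 fold change of -1.18. Cdh1, the adhesion protein of epithelial cells (ENSMUSG00000000303, chromosome 8, 106603351 to 106670246), was at 6.27 ± 0.194 and 2.64 ± 0.128 FPKM in D4_DUX and D4, a log2 fold change of 1.00 (SE 0.06, adjusted p = 9.97e-07). Krt8, a keratin of simple epithelia (ENSMUSG00000049382, chromosome 15, 101996698 to 102004482), was at 10.3 ± 0.886 and 2.57 ± 0.351 FPKM, a log2 fold change of 1.66 (SE 0.09, adjusted p = 5.36e-07). As a list the epithelial genes did not pass camera, with 7 of 27 higher and 2 lower (adjusted p = 0.29). Postn, a matrix protein of fibroblasts (ENSMUSG00000027750, chromosome 3, 54361109 to 54391037), was at 11.9 ± 0.651 and 45.2 ± 1.83 FPKM, a log2 fold change of -1.84 (SE 0.13, adjusted p = 3.24e-06). Lyz2, the lysozyme of macrophages (ENSMUSG00000069516, chromosome 10, 117277331 to 117282321), was at 31 ± 1.23 and 149 ± 14.5 FPKM, a log2 fold change of -2.22 (SE 0.11, adjusted p = 2.02e-07).

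**Figure D1:**
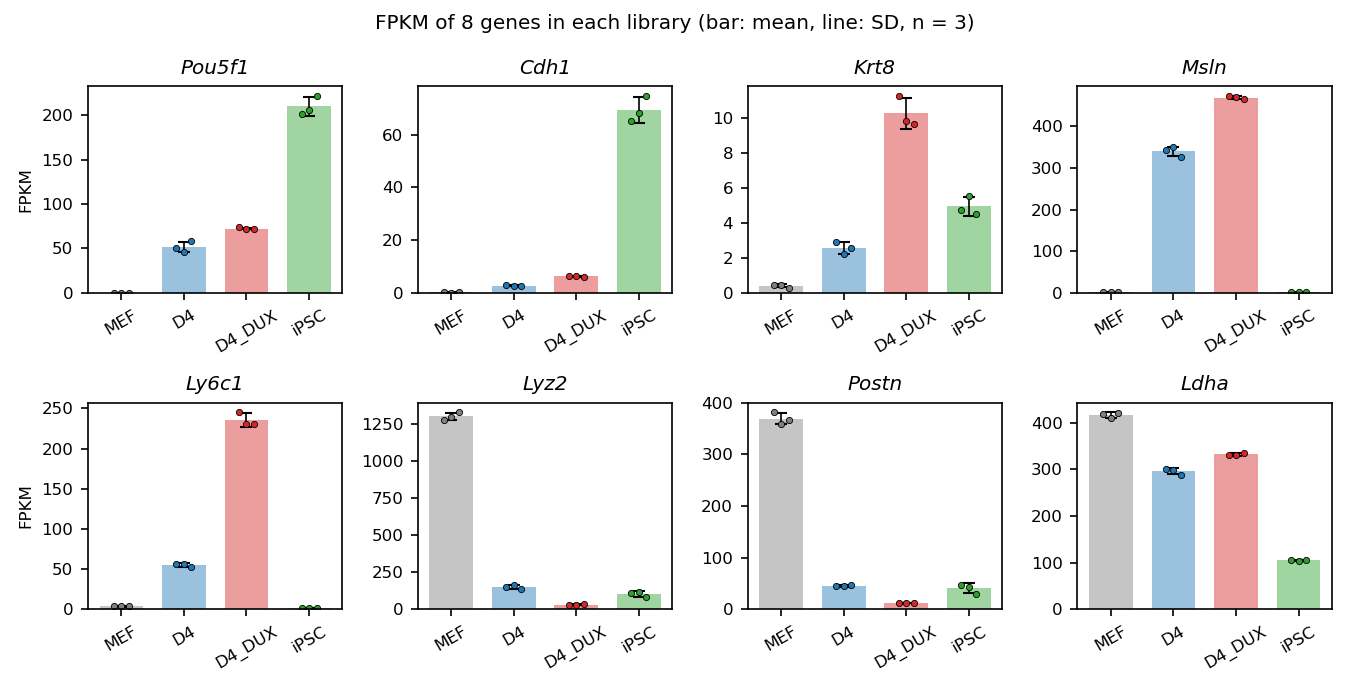
FPKM of 8 genes on linear axes from 0, with 1 panel per gene; points are the 3 libraries of each group (MEF, D4, D4_DUX, iPSC), bars their mean and lines the SD. Krt8 sits at 10.3 in D4_DUX and 2.57 in D4, and Lyz2 at 31 and 149, while Pou5f1 reaches 210 in iPSC.

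The highest log2 fold change was that of Ly6c1, a surface protein anchored by lipid (ENSMUSG00000079018, chromosome 15, 75044018 to 75048830), at 235 ± 8.79 and 55 ± 2.58 FPKM in D4_DUX and D4, a log2 fold change of 2.08 (SE 0.11, adjusted p = 3.2e-07). Hist1h4m, a histone H4 gene, was at 48.4 ± 2.84 and 11.2 ± 2.23 FPKM (log2 fold change 2.02, adjusted p = 2.69e-06). As polyadenylated RNA was selected, its values cover only the messages that this selection took up. Oas2, an interferon-induced enzyme, Cck, a peptide hormone, and Slurp1, a secreted relative of the Ly6 proteins, rose with log2 fold changes of 1.67, 1.59 and 1.53 (adjusted p = 6.52e-05, 1.01e-05 and 1.11e-08). The antisense gene Efhd1os and the microRNA gene Mir7028 completed the top 8 with 1.69 and 1.57 (adjusted p = 4.95e-05 and 0.0044); whether counting used the strand is not given in the sources used here, so it is open whether fragments of overlapping genes were counted there. At the other end, 6 of the 8 genes are known from macrophages and other myeloid cells. Lyz2 and the chemokines Ccl3 and Ccl6 fell (log2 fold changes -2.22, -2.31 and -1.96), and Wfdc17, the protease Mmp9 and the receptor Marco fell (log2 fold changes -2.16, -2.10 and -1.81). The remaining genes of this end were Postn and Egr1, a transcription factor induced by growth signals, which was at 7.89 ± 0.388 and 30.7 ± 2.63 FPKM, a log2 fold change of -1.83 (SE 0.07, adjusted p = 7.33e-08).

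Each of the 4 transgene factors rose in the libraries labelled D4_DUX, and all 4 were also higher when adjusted over the list alone. Pou5f1 was at 72.3 ± 1.04 and 51.6 ± 6 FPKM in D4_DUX and D4 (log2 fold change 0.49, adjusted p = 0.00027) and Sox2 at 95.1 ± 4.21 and 67.4 ± 7.39 FPKM (0.49, adjusted p = 0.00185, and 0.0557 with a pseudocount of 0.1). Klf4 was at 127 ± 4.01 and 98 ± 2.49 FPKM (0.37, adjusted p = 0.0056) and Myc at 132 ± 4.56 and 106 ± 2.54 FPKM (0.31, adjusted p = 0.0124). The table does not separate transgene from endogenous messages. The other pluripotency genes did not pass as a list: 2 of 30 were higher and 3 lower, or 1 and 2 adjusted over the list alone (camera adjusted p = 0.593). Klf5 and Tbx3 fell (log2 fold changes -0.36 and -0.29).

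Among the epithelial genes 7 of 27 rose and 2 fell, with the same counts adjusted over the list alone, and the list did not pass its test (camera adjusted p = 0.29). With fry, which does not set a list against other genes, its adjusted p was 0.000752. Krt8, Cdh1 and Krt19 rose, the last from 3.53 ± 0.291 to 9.66 ± 0.869 FPKM (log2 fold change 1.23, adjusted p = 1.06e-06), and Cdh3, the placental cadherin, fell by 0.61. The mesenchymal genes were lower as a list, with 15 of 30 lower and 6 higher, or 16 and 6 adjusted over the list alone. Their median log2 fold change was -0.25 (camera adjusted p = 0.0011, and adjusted p = 0.546 with an estimated correlation). Ccn1 was at 205 ± 8.12 and 447 ± 23.6 FPKM in D4_DUX and D4 (-1.12, adjusted p = 2.02e-07). Ccn2, which responds to TGF-beta and to mechanical load, fell from 172 ± 10.7 to 53.9 ± 3.93 FPKM (-1.66). The 6 higher members, named after their values were seen, were Snai2 (0.48), Tgfbr2 (0.44), S100a4 (0.4), Zeb2 (0.3), Cdh2 (0.3) and Vim (0.17). Fibroblast matrix genes were lower as well, 16 of 26 against 3 higher, or 19 and 3 adjusted over the list alone, with a median of -0.30 (camera adjusted p = 6.05e-07, and adjusted p = 0.546 with an estimated correlation). Beside Postn, the growth factor receptor Pdgfra (9.58 ± 0.861 and 17.5 ± 1.53 FPKM, -0.81), the protease Fap (-0.75) and the collagen Col12a1 (-0.76) fell.

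Metabolic lists split. Cholesterol synthesis genes were lower, 17 of 22 against 1 higher, or 18 and 1 adjusted over the list alone, with a median of -0.36 (camera adjusted p = 2.52e-09, and adjusted p = 0.217 with an estimated correlation). Msmo1, an enzyme of sterol demethylation, was at 6.82 ± 0.273 and 11.5 ± 0.219 FPKM in D4_DUX and D4 (-0.68, adjusted p = 8.61e-07). Glycolysis and lactate genes went both ways, 7 of 25 higher and 6 lower, or 7 and 7 adjusted over the list alone, and the list did not pass (camera adjusted p = 0.985). Ldha, which converts pyruvate to lactate (ENSMUSG00000063229, chromosome 7, 46841475 to 46855627), rose from 296 ± 6.29 to 333 ± 3.16 FPKM (0.17, adjusted p = 0.00116), and Pkm rose from 496 ± 10.9 to 598 ± 9.08 FPKM (0.27). Eno3 rose by 0.53 on the log2 scale, and Ldhb, the subunit of the heart form of lactate dehydrogenase, and Pfkm fell (log2 fold changes -0.47 and -0.30). Of 52 nuclear genes of oxidative phosphorylation 0 were higher and 3 lower, 0 and 0 adjusted over the list alone (camera adjusted p = 0.335). The tricarboxylic acid cycle had 1 of 19 higher and 5 lower, the same adjusted over the list alone (camera adjusted p = 0.197). The list passed downward with quantile normalization (adjusted p = 0.0253) and passed with fry (adjusted p = 0.0456). Idh2 and Cs, members that fell, had -0.23 and -0.14. Serine and one-carbon metabolism had 2 of 16 higher and 1 lower, or 1 and 1 adjusted over the list alone (camera adjusted p = 0.985), and its median of 0.04 and camera's direction, downward, differ in sign.

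The histone lactylation enzymes, a list of writers, erasers and genes related to lactyl-CoA, did not pass camera. Of 20 genes 7 were higher and 1 lower, the same adjusted over the list alone (camera adjusted p = 0.276, and adjusted p = 0.0232 with fry). The deacetylase Hdac1 rose from 32.6 ± 0.581 to 39.2 ± 1.32 FPKM (0.26, adjusted p = 0.00025), Aars rose by 0.19 on the log2 scale, and Acss2 fell by 0.29. Ep300, an acetyltransferase, was at 8.08 ± 0.215 and 7.14 ± 0.486 FPKM (0.16, adjusted p = 0.028), a call that did not hold without D4 replicate 1 (adjusted p = 0.0702), D4 replicate 2 (0.0996), D4_DUX replicate 1 (0.0809) or D4_DUX replicate 3 (0.0844), nor under 4 other settings (0.0528 to 0.0761). Smarca4 (ENSMUSG00000032187, chromosome 9, 21616169 to 21704230), the ATPase of the BAF complex, was at 40.6 ± 0.825 and 36.8 ± 1.4 FPKM in D4_DUX and D4 (0.14, SE 0.04, adjusted p = 0.0145). Its call ended with median-ratio scaling (adjusted p = 0.0604), quantile normalization (0.13), without D4 replicate 2 (0.053) and without D4_DUX replicate 1 (0.0592). BAF complex subunits were higher in 8 of 25 cases and lower in 0, or 7 and 0 adjusted over the list alone, with a median of 0.08 (camera adjusted p = 0.0251, and adjusted p = 0.546 with an estimated correlation). The list's call ended with median-ratio scaling (adjusted p = 0.0542) and quantile normalization (0.0848). Ss18, Arid1a and Smarce1 had log2 fold changes of 0.30, 0.30 and 0.22.

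Macrophage markers were lower in 14 of 16 cases and higher in 0, the same adjusted over the list alone, with a median of -1.18 (camera adjusted p = 2.26e-11, and adjusted p = 0.0717 with an estimated correlation). The complement gene C1qa was at 0.418 ± 0.174 and 3.25 ± 0.267 FPKM in D4_DUX and D4, and Cd68 at 3.53 ± 0.432 and 9.26 ± 0.466 FPKM. Immediate early genes, which respond within minutes to growth factors or stress, fell beside them in 11 of 15 cases against 1 higher, the same adjusted over the list alone, with a median of -0.59 (camera adjusted p = 5.31e-09, and adjusted p = 0.111 with an estimated correlation). Fos was at 8.09 ± 0.541 and 24.6 ± 3.21 FPKM (-1.49, adjusted p = 5.36e-07), and Zfp36 and Nr4a1 fell (log2 fold changes -1.31 and -0.84). Interferon response genes were higher, 15 of 30 against 1 lower, or 18 and 1 adjusted over the list alone, with a median of 0.62 (camera adjusted p = 0.000305, and adjusted p = 0.69 with an estimated correlation). Oas2 was at 24 ± 0.183 and 7.11 ± 2.35 FPKM, and Oas1a and Stat2 had 1.02 and 0.86. The member that fell was Ccl5, a chemokine also made by immune cells, at 1.07 ± 0.236 and 4.39 ± 1.37 FPKM (-1.36), beside the lower macrophage markers.

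Cell cycle genes were lower in 15 of 34 cases and higher in 3, or 20 and 6 adjusted over the list alone, with a median of -0.15 (camera adjusted p = 0.00599, and adjusted p = 0.546 with an estimated correlation). Cdc20, an activator of the exit from mitosis, fell by 0.29 (adjusted p = 0.00017), and Ccna2 and Top2a fell (log2 fold changes -0.25 and -0.26). Neural markers were higher in 5 of 8 cases and lower in 0, or 6 and 0 adjusted over the list alone, with a median of 0.25 (camera adjusted p = 0.00838, and adjusted p = 0.111 with an estimated correlation). Nes, an intermediate filament of progenitor cells, was at 27.4 ± 1.63 and 16.4 ± 0.623 FPKM (0.71) and Tubb3 at 27.4 ± 0.774 and 19.4 ± 1.1 FPKM (0.48). The p53 targets had 6 of 24 higher and 7 lower, or 6 and 9 adjusted over the list alone (camera adjusted p = 0.354), with Ckap2 and Plk2 at -0.61 and -0.44. Stress genes had 3 of 18 higher and 1 lower (camera adjusted p = 0.985), endothelial markers 3 of 7 and 2 (0.593), endoderm markers 1 of 11 and 2 (0.29) and trophoblast markers 1 of 6 and 2 (0.985). Skeletal muscle markers, 4 tested, had 1 higher and 1 lower and were not tested as a list. Adjusted over the list alone these counts were the same except for 3 endothelial and 2 muscle markers lower.

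In all, 3432 of 17114 genes were higher and 2634 lower in the libraries labelled D4_DUX than in D4, 72 and 114 of them by at least 2-fold, and the groups' values did not overlap for 50.5% of genes against 10% by chance. Of 21 lists tested, 9 passed camera at the preset correlation and 0 with an estimated correlation, where the smallest adjusted p was 0.0717. The balance of directions depends on scaling: with median-ratio scaling 2840 genes were higher and 2986 lower, and with quantile normalization 2827 and 2750. The counts at 2-fold became 121 and 183 with a pseudocount of 0.5 and 204 and 346 with a pseudocount of 0.1. They became 162 and 229 after rescaling to TPM and 243 and 490 with voom. They were lower with FPKM of at least 5 (46 and 102) and among protein-coding genes (41 and 99).

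**Figure D2:**
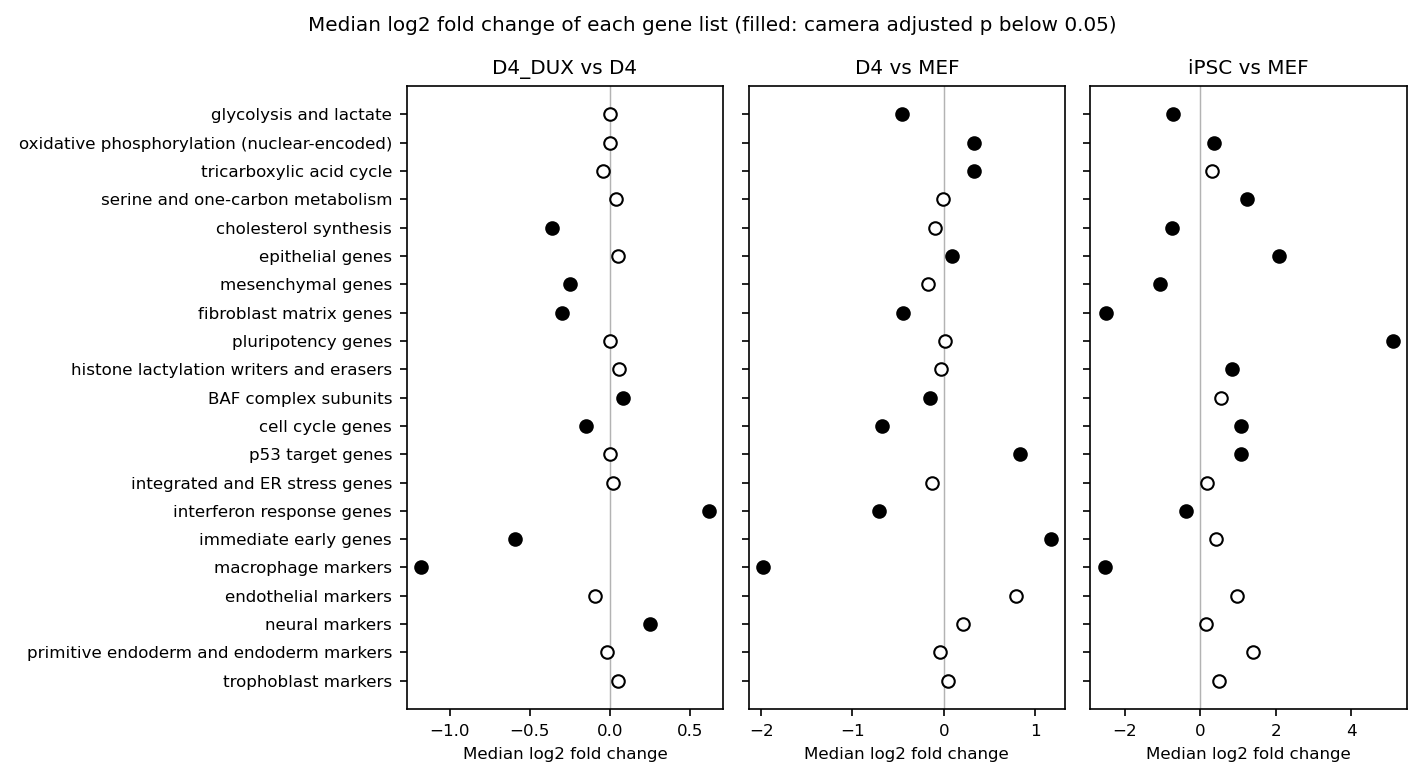
Median log2 fold change (horizontal axis) of the tested members of each of 21 gene lists (vertical axis) in the 3 comparisons; filled circles are lists with a camera adjusted p below 0.05 at the preset correlation, open circles the others. In D4_DUX against D4 the macrophage markers lie lowest, at -1.18, and the interferon response genes highest, at 0.62.

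The comparison of D4 with MEF sets reprogramming cultures against fibroblasts, with the overexpression control labelled on the D4 side only. The labels do not say whether both came from the same preparation of fibroblasts. Genes of oxidative phosphorylation rose (40 of 52, camera adjusted p = 3.07e-05, and adjusted p = 0.598 with an estimated correlation) and cell cycle genes fell (32 of 34, camera adjusted p = 1.52e-11, and adjusted p = 0.121 with an estimated correlation). Lists that fell stood beside macrophage markers with a median log2 fold change of -1.98. Aldh3a1, an aldehyde dehydrogenase of surface epithelia (ENSMUSG00000019102, chromosome 11, 61207537 to 61218421), was at 194 ± 2.94 and 0.036 ± 0.0153 FPKM in D4 and MEF, a log2 fold change of 7.56 (SE 0.05, adjusted p = 3.05e-15). Msln, the mesothelial surface protein (ENSMUSG00000063011, chromosome 17, 25748613 to 25754378), was at 340 ± 11.9 and 1.45 ± 0.414 FPKM, a log2 fold change of 7.13 (SE 0.10, adjusted p = 3.91e-13). Nccrp1, Prelp, Clec3b and Itgb4, an integrin of epithelia, followed with log2 fold changes of 6.71, 6.21, 6.16 and 5.74.

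At the low end, Rpsa-ps10, a processed pseudogene (ENSMUSG00000047676, chromosome 3, 150072658 to 150073542), was at 6.24 ± 0.363 and 528 ± 28 FPKM in D4 and MEF, and Ifi202b, an interferon-inducible gene that differs between mouse strains (ENSMUSG00000026535, chromosome 1, 173962568 to 173982744), was listed at 0 in all 3 D4 libraries and at 62.4 ± 6.89 FPKM in MEF. Rpsa-ps10, Tpm3-rs7 and Rpl29 fell (log2 fold changes -6.19, -3.94 and -3.87). Together with Ifi202b and Igfbp5 these belong to a set, chosen after its values were seen, of 23 genes with FPKM of at least 5 in every MEF and iPSC library and at least 8 times the FPKM of every day 4 library, of which 14 were processed pseudogenes. The matrix protein Thbs4 fell by 3.92 and Igfbp5, which binds insulin-like growth factors, fell by 3.79. The macrophage genes Ccl12 and Marco fell (log2 fold changes -4.58 and -3.76, adjusted p = 1.19e-08 and 7.34e-10).

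The 4 transgene factors rose, also adjusted over the list alone. Pou5f1 (ENSMUSG00000024406, chromosome 17, 35506018 to 35510772) was listed at 0 FPKM in all 3 MEF libraries and at 51.6 ± 6 FPKM in D4 (adjusted p = 9.18e-14), and Sox2, Klf4 and Myc were at 67.4 ± 7.39, 98 ± 2.49 and 106 ± 2.54 FPKM in D4 against 0.449 ± 0.182, 9.41 ± 1.06 and 14 ± 2.2 in MEF. Of the other pluripotency genes 3 of 30 were higher and 5 lower, the same adjusted over the list alone (camera adjusted p = 0.817), with a median of 0.01 and a test direction below 0. L1td1, an RNA-binding protein of pluripotent cells, rose from 0.0164 ± 0.0144 to 3.79 ± 0.164 FPKM, and Klf2 fell by 1.93.

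Epithelial genes passed upward with 10 of 27 higher and 2 lower, the same adjusted over the list alone, a median of 0.09 and a mean of 0.46 (camera adjusted p = 0.0409, and adjusted p = 0.262 with an estimated correlation). Cdh1 was at 2.64 ± 0.128 and 0.137 ± 0.076 FPKM in D4 and MEF (1.68, adjusted p = 7.43e-10), the junction proteins Jup and Dsp had 1.84 and 2.32, and Cdh3 fell by 1.11. Fibroblast matrix genes were lower, 18 of 26 against 4 higher, or 19 and 4 adjusted over the list alone, with a median of -0.45 (camera adjusted p = 0.00115, and adjusted p = 0.633 with an estimated correlation). Postn was at 45.2 ± 1.83 and 369 ± 11.3 FPKM and Pdgfra at 17.5 ± 1.53 and 85.2 ± 4.1 FPKM, while Timp3, an inhibitor of matrix proteases, rose to 530 ± 11.8 from 68.5 ± 3.8 FPKM. Mesenchymal genes went both ways, 10 of 30 higher and 13 lower, or 10 and 14 adjusted over the list alone (camera adjusted p = 0.476), with S100a4 at 614 ± 19.4 and 156 ± 17 FPKM (1.97).

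Glycolysis and lactate genes were lower at day 4, 18 of 25 against 6 higher, the same adjusted over the list alone, with a median of -0.46 (camera adjusted p = 0.00114, and adjusted p = 0.198 with an estimated correlation). Ldha was at 296 ± 6.29 and 417 ± 5.29 FPKM in D4 and MEF (-0.49, adjusted p = 4.56e-08) and Eno1 at 233 ± 1.91 and 407 ± 8.16 FPKM (-0.80). Slc16a1, a lactate transporter, fell by 1.11, and Pfkfb4 rose by 1.46. Oxidative phosphorylation genes were higher, 40 of 52 against 1 lower, or 42 and 1 adjusted over the list alone, with a median of 0.33 (camera adjusted p = 3.07e-05, and adjusted p = 0.598 with an estimated correlation). Uqcrc1 of respiratory complex III and Sdha of complex II had 0.69 and 0.40. The tricarboxylic acid cycle was higher in 17 of 19 cases and lower in 1, the same adjusted over the list alone, also with a median of 0.33 (camera adjusted p = 0.000201, and adjusted p = 0.196 with an estimated correlation). Pdha1, a subunit of pyruvate dehydrogenase, was at 71.6 ± 2.13 and 42.8 ± 2.21 FPKM (0.73). Serine and one-carbon metabolism had 6 of 16 higher and 6 lower (camera adjusted p = 0.592) and cholesterol synthesis 5 of 22 and 10 (0.149), the same adjusted over the list alone.

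Cell cycle genes fell in 32 of 34 cases against 1 higher, the same adjusted over the list alone, with a median of -0.68 (camera adjusted p = 1.52e-11, and adjusted p = 0.121 with an estimated correlation). Top2a and the mitotic kinase Cdk1 fell (log2 fold changes -0.84 and -0.77). The p53 targets were higher in 21 of 24 cases and lower in 2, the same adjusted over the list alone, with a median of 0.83 (camera adjusted p = 4e-07, and adjusted p = 0.111 with an estimated correlation). Perp, which also serves desmosomes, rose from 0.807 ± 0.0971 to 66.3 ± 1.02 FPKM, and Cdkn1a, the inhibitor p21, from 68.8 ± 1.16 to 197 ± 4.35 FPKM. Immediate early genes were higher in 13 of 15 cases and lower in 2, the same adjusted over the list alone, with a median of 1.17 (camera adjusted p = 0.00013, and adjusted p = 0.251 with an estimated correlation). Nr4a1 and Fos rose by 3.40 and 2.56.

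Macrophage markers were lower in 16 of 16 cases, the same adjusted over the list alone, with a median of -1.98 (camera adjusted p = 2.89e-11, and adjusted p = 0.0796 with an estimated correlation). Lyz2 was at 149 ± 14.5 and 1300 ± 22.7 FPKM in D4 and MEF. Interferon response genes fell beside them in 18 of 30 cases against 1 higher, the same adjusted over the list alone, with a median of -0.71 (camera adjusted p = 0.00243, and adjusted p = 0.682 with an estimated correlation). Stat2 fell by 1.09, and Oas2 rose by 1.42. BAF complex subunits were lower in 14 of 25 cases and higher in 5, the same adjusted over the list alone, with a median of -0.15 (camera adjusted p = 0.0414, and adjusted p = 0.598 with an estimated correlation). Phf10 and Pbrm1 fell (log2 fold changes -0.73 and -0.55), and the ATPases Smarca4 (36.8 ± 1.4 and 28.5 ± 0.814 FPKM, 0.36, adjusted p = 7.34e-06) and Smarca2 (0.51) rose. Histone lactylation enzymes had 6 of 20 higher and 8 lower, or 7 and 8 adjusted over the list alone (camera adjusted p = 0.827), with a mean of 0.03 but a median of -0.03 and a test direction below 0. Hagh rose by 1.46, and Ep300 was at 7.14 ± 0.486 and 8.03 ± 0.322 FPKM (-0.15, adjusted p = 0.0199, and 0.0796 without MEF replicate 1, 0.0501 without D4 replicate 1, 0.0816 without D4 replicate 2 and 0.0604 with only the groups compared). Stress genes had 3 of 18 higher and 9 lower (camera adjusted p = 0.19), endothelial markers 4 of 7 and 2 (0.398), neural markers 4 of 8 and 3 (0.917), endoderm markers 2 of 11 and 4 (0.476), and trophoblast markers 3 of 6 and 2 (0.987; median 0.05, test direction below 0). Muscle markers had 2 of 4 higher and 1 lower, and of the 2-cell-stage genes Zfp750 rose by 1.38 and Nelfa fell by 0.28. All of these counts were the same adjusted over the list alone.

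In all, 5858 genes were higher and 4720 lower in D4 than in MEF, 901 and 733 by at least 2-fold, and values did not overlap for 66.5% of genes against 10% by chance. Of 21 lists, 11 passed camera at the preset correlation and 0 with an estimated correlation, where the smallest adjusted p was 0.0796. The balance of directions turned with scaling, to 5086 higher and 5554 lower with median-ratio scaling and 5155 and 5386 with quantile normalization. The counts at 2-fold became 1462 and 1237 with a pseudocount of 0.1, and 1598 and 1352 with voom. They were lower with FPKM of at least 5 (637 and 460) and among protein-coding genes (736 and 544).

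The comparison of iPSC with MEF sets induced pluripotent stem cells against fibroblasts. Pluripotency genes rose (30 of 30, camera adjusted p = 2.67e-12, and adjusted p = 0.149 with an estimated correlation) and fibroblast matrix genes fell (25 of 26, camera adjusted p = 2.92e-12, and adjusted p = 0.187 with an estimated correlation). Lists that fell stood beside macrophage markers with a median log2 fold change of -2.53. Dppa5a, an RNA-binding protein of pluripotent cells (ENSMUSG00000060461, chromosome 9, 78367052 to 78368177), was at 681 ± 25.1 and 0.0459 ± 0.0794 FPKM in iPSC and MEF, a log2 fold change of 9.35 (SE 0.06, adjusted p = 1.16e-15). Pou5f1 was at 210 ± 10.8 FPKM in iPSC and listed at 0 in all 3 MEF libraries, and Nanog, a core factor of pluripotency, was at 112 ± 13.9 and 0.201 ± 0.0477 FPKM. Tdgf1, Utf1, L1td1 and Sox2 had log2 fold changes of 7.66, 7.05, 7.01 and 6.52, and Tdh, the threonine dehydrogenase of mouse pluripotent cells, was listed at 0 in MEF and at 95.2 ± 5.18 FPKM in iPSC. Aspn, a matrix proteoglycan (ENSMUSG00000021388, chromosome 13, 49544443 to 49567565), was at 1.09 ± 0.35 and 71.5 ± 3.17 FPKM in iPSC and MEF, a log2 fold change of -5.13 (SE 0.10, adjusted p = 9.63e-13). Ndufa4l2, Ptn, Itga11, Lrrc17, Fbn2 and Igfbp3 fell (log2 fold changes -5.01, -4.52, -4.44, -4.40, -4.39 and -4.37), and the matrix gene Tnn completed the 8 lowest. Klf4 rose from 9.41 ± 1.06 to 55.5 ± 6.68 FPKM and Myc from 14 ± 2.2 to 21.5 ± 0.901 FPKM, and with Pou5f1 and Sox2 all 4 transgene factors were higher, also adjusted over the list alone.

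Pluripotency genes were higher in 30 of 30 cases, the same adjusted over the list alone, with a median of 5.10 (camera adjusted p = 2.67e-12, and adjusted p = 0.149 with an estimated correlation). Epithelial genes were higher in 25 of 27 cases and lower in 2, the same adjusted over the list alone, with a median of 2.09 (camera adjusted p = 1.29e-05, and adjusted p = 0.0614 with an estimated correlation). Cdh1 was at 69.4 ± 4.86 and 0.137 ± 0.076 FPKM in iPSC and MEF (5.95) and Epcam at 53 ± 2.7 and 0.121 ± 0.0244 FPKM (5.59). Fibroblast matrix genes were lower in 25 of 26 cases and higher in 1, the same adjusted over the list alone, with a median of -2.51 (camera adjusted p = 2.92e-12, and adjusted p = 0.187 with an estimated correlation). Col3a1 was at 109 ± 13.6 and 824 ± 23.4 FPKM. Mesenchymal genes were lower in 25 of 30 cases and higher in 4, the same adjusted over the list alone, with a median of -1.07 (camera adjusted p = 1.11e-08, and adjusted p = 0.187 with an estimated correlation). Lox, which links collagen fibres, and Tgfb3 fell (log2 fold changes -2.78 and -2.66).

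Glycolysis and lactate genes were lower in 19 of 25 cases and higher in 5, the same adjusted over the list alone, with a median of -0.73 (camera adjusted p = 1.29e-05, and adjusted p = 0.0879 with an estimated correlation). Ldha was at 105 ± 0.782 and 417 ± 5.29 FPKM in iPSC and MEF (-1.98, adjusted p = 1.55e-13), the lactate exporter Slc16a3 fell by 3.82, and the glucose transporter Slc2a3 rose from 2.03 ± 0.0918 to 84.2 ± 6.63 FPKM. Oxidative phosphorylation genes were higher in 40 of 52 cases and lower in 1, the same adjusted over the list alone, with a median of 0.36 (camera adjusted p = 0.0175, and adjusted p = 0.693 with an estimated correlation), a call that median-ratio scaling ends (adjusted p = 0.142). Atp5b and Atp5a1 of the ATP synthase rose by 1.07 and 0.99. Serine and one-carbon metabolism was higher in 15 of 16 cases and lower in 1, the same adjusted over the list alone, with a median of 1.24 (camera adjusted p = 0.000626, and adjusted p = 0.0614 with an estimated correlation). Gldc, of glycine cleavage, was at 24.9 ± 1.55 and 0.0925 ± 0.0225 FPKM. Cholesterol synthesis was lower in 19 of 22 cases and higher in 1, the same adjusted over the list alone, with a median of -0.76 (camera adjusted p = 3.61e-07, and adjusted p = 0.187 with an estimated correlation). Hmgcs1 was at 11.5 ± 0.504 and 44.6 ± 1.71 FPKM. The tricarboxylic acid cycle had 12 of 19 higher and 3 lower, the same adjusted over the list alone (camera adjusted p = 0.338), with Pdhb at 1.91.

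Cell cycle genes were higher in 30 of 34 cases and lower in 2, the same adjusted over the list alone, with a median of 1.09 (camera adjusted p = 1.18e-05, and adjusted p = 0.187 with an estimated correlation), and Mcm2, of the replicative helicase, was at 59.9 ± 3.38 and 9.18 ± 0.249 FPKM in iPSC and MEF. The p53 targets were higher in 22 of 24 cases and lower in 2, the same adjusted over the list alone, with a median of 1.08 (camera adjusted p = 0.000261, and adjusted p = 0.161 with an estimated correlation). Histone lactylation enzymes were higher in 16 of 20 cases and lower in 3, the same adjusted over the list alone, with a median of 0.84 (camera adjusted p = 0.0229, and adjusted p = 0.361 with an estimated correlation). Hdac1 was at 88.7 ± 2.93 and 29.1 ± 0.641 FPKM and Ep300 at 16.3 ± 0.625 and 8.03 ± 0.322 FPKM. BAF complex subunits had 16 of 25 higher and 7 lower, the same adjusted over the list alone (camera adjusted p = 0.389). Smarcd1 rose by 2.19, and Smarca4 was at 35.8 ± 1.26 and 28.5 ± 0.814 FPKM (0.32, adjusted p = 8.74e-06, and 0.0807 with quantile normalization).

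Macrophage markers were lower in 15 of 16 cases and higher in 1, the same adjusted over the list alone, with a median of -2.53 (camera adjusted p = 2.02e-07, and adjusted p = 0.0879 with an estimated correlation), and Lyz2 was at 103 ± 17.7 and 1300 ± 22.7 FPKM in iPSC and MEF. Interferon response genes were lower beside them in 13 of 30 cases and higher in 5, or 11 and 4 adjusted over the list alone, with a median of -0.39 (camera adjusted p = 0.0453, and adjusted p = 0.717 with an estimated correlation). That call ended with median-ratio scaling (adjusted p = 0.0867) and quantile normalization (0.148). Immediate early genes had 9 of 15 higher and 3 lower (camera adjusted p = 0.436), endothelial markers 6 of 7 and 1 (0.158), endoderm markers 7 of 11 and 3 (0.378) and trophoblast markers 3 of 6 and 1 (0.436). Stress genes had 9 of 18 higher and 7 lower, or 11 and 7 adjusted over the list alone (camera adjusted p = 0.45; median 0.17), and neural markers 4 of 8 and 3 (0.724; median 0.16), both with a test direction below 0. Muscle markers had 2 of 4 higher and 1 lower, and the 2-cell-stage genes Zfp750 and Nelfa rose by 2.14 and 0.76. Counts without a second pair were the same adjusted over the list alone.

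In all, 8733 genes were higher and 5335 lower in iPSC than in MEF, 3436 and 1466 by at least 2-fold, and values did not overlap for 82.4% of genes against 10% by chance. Of 21 lists, 13 passed camera at the preset correlation and 0 with an estimated correlation, where the smallest adjusted p was 0.0614. The balance of directions depends on scaling: the median log2 fold change of all genes was 0.21 as deposited and -0.07 after quantile normalization, with which 6609 genes were higher and 7561 lower, 2390 and 2481 by at least 2-fold. With voom 2258 were lower by at least 2-fold.

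The positions of the libraries along the direction from MEF (0) to iPSC (1) were compared. D4 was at 0.145 ± 0.00131 (SD, n = 3) and D4_DUX at 0.195 ± 0.00387 (SD, n = 3). The difference of 0.0498 exceeded the spread of both groups, and all 3 libraries labelled D4_DUX lay above all 3 D4 libraries. The exact two-sided permutation p was 0.1, the smallest that 3 against 3 libraries allow. The position describes this direction and not the distance to iPSC. Nor does it measure progress in reprogramming, since the labels do not say whether D4 and MEF came from the same preparation of fibroblasts. In a measure chosen after the results were seen, the root mean square log2 difference from the iPSC mean over the same 17114 genes was 1.185 to 1.189 in the libraries labelled D4_DUX, 1.179 to 1.18 in D4 and 1.136 to 1.141 in MEF, so the former were not nearer to iPSC overall. Across 17114 genes, the change from D4 to D4_DUX and the change from MEF to iPSC had a Spearman's rho of 0.19 and a Pearson's r of 0.2. Of 5250 genes called in both comparisons 3579 (68.2%) had the same sign, against 50.6% if the directions were independent. Of these, 2068 were higher in both, Cdh1 and Pou5f1 among them, and 1511 lower in both, such as Tgfb3 and Lyz2. Transgene and endogenous messages of Pou5f1 are not separated. A shared sign is not a move to the iPSC level: Lyz2 was at 149, 31 and 103 FPKM in D4, D4_DUX and iPSC. The macrophage markers, lower in the libraries labelled D4_DUX and in iPSC, are part of the shared direction.

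**Figure D3:**
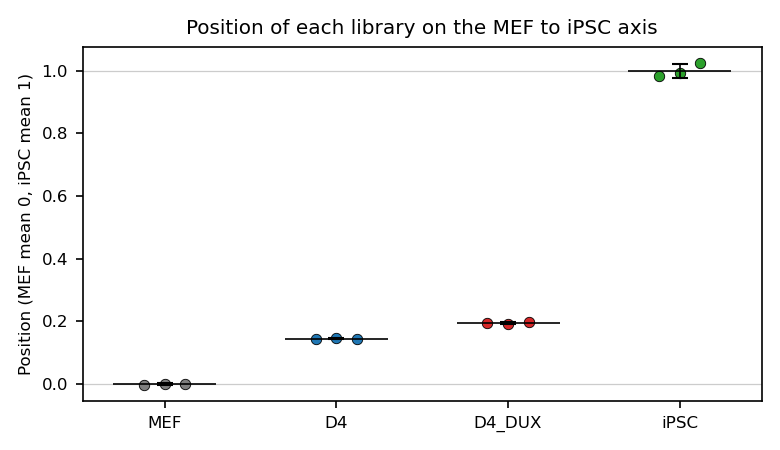
Position of each library (points) on the axis from the MEF mean (0) to the iPSC mean (1), by group, with the mean and SD of n = 3 libraries as lines. The 3 D4_DUX libraries sit between 0.1916 and 0.199, above the 3 D4 libraries between 0.1437 and 0.1463.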

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

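The alternatives chosen only after the results were seen are limma voom on recovered fragments, protein-coding genes only, and the list tests with rescaling to TPM and with quantile normalization. No called list, position, rho or called named gene changed its direction under any alternative run, the 6 higher mesenchymal genes of D4_DUX against D4 left aside. The balance of genes higher and lower did turn, with median-ratio scaling in D4_DUX against D4 (2840 and 2986), with median-ratio scaling (5086 and 5554) and quantile normalization (5155 and 5386) in D4 against MEF, and with quantile normalization in iPSC against MEF (6609 and 7561). Counts of genes at the adjusted p threshold stayed within 1.5 times the reported ones except under the filters, where the number of genes tested sets the count: with FPKM of at least 5 (10501 genes tested) 3087 genes were lower in D4 against MEF and 5570 higher in iPSC against MEF, and with no filter (40384 genes tested) 13594 were higher in iPSC against MEF. Counts at 2-fold moved further, over the alternatives that keep all libraries from 41 to 243 higher and from 99 to 490 lower in D4_DUX against D4, from 637 to 1598 and from 460 to 1352 in D4 against MEF, and from 2262 to 4556 and from 1115 to 2481 in iPSC against MEF. Each highest count came with voom, apart from the 2481 with quantile normalization. Over the alternatives that keep all libraries, genes higher and lower in D4_DUX against D4 ranged from 2709 to 3602 and from 1794 to 2986, and without 1 library at a time from 2645 to 3030 and from 2130 to 2334. In D4 against MEF, leaving out libraries gave 5504 to 5702 and 4385 to 4518, and in iPSC against MEF 8501 to 8625 and 5152 to 5308. With voom the counts for D4_DUX against D4 were 3602 and 2844, and among protein-coding genes 3188 and 2565. Scaling moved single genes across 0 in iPSC against MEF, where 24 genes were called the opposite way with median-ratio scaling and 243 with quantile normalization, against 0 in the other comparisons. With the replicate number as a block the counts were 3182 and 2495, 5746 and 4635, and 8691 and 5283, and 9, 11 and 13 lists passed. The labels do not say whether the numbers pair the libraries. After removal of group means, libraries of 1 number correlated at -0.02 to 0.05 in D4_DUX and D4, and those of different numbers at -0.08 to 0.06. In iPSC and MEF the ranges were -0.15 to 0.06 and -0.13 to 0.22. A shared effect of the number was not seen, which does not exclude a pairing.

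With camera at an estimated correlation 0 lists passed in D4_DUX against D4, 0 in D4 against MEF and 0 in iPSC against MEF. The cause was not tested. A higher correlation alone does not account for every loss, so 0 lists passing is no measure of the correlation between genes. In D4_DUX against D4, neural markers, with an estimated correlation of -0.1, went from camera adjusted p = 0.00838 to 0.111. In iPSC against MEF, serine and one-carbon metabolism, estimated at the preset 0.01, went from 0.000626 to 0.0614. With fry, which does not set a list against other genes, 14, 19 and 20 lists passed. Adjusted p over the alternatives ran from 0.00273 to 0.546 for BAF subunits and from 0.0253 to 0.63 for the tricarboxylic acid cycle in D4_DUX against D4, and in iPSC against MEF from 9.64e-06 to 0.693 for oxidative phosphorylation and from 0.0439 to 0.717 for interferon response genes (0.271 with fry). The position difference was 0.0407 to 0.051 over the alternatives and 0.0476 to 0.0513 without 1 library at a time. The rho across genes was 0.22 with only the genes called in iPSC against MEF, 0.21 with FPKM of at least 5, with median-ratio scaling and with quantile normalization, and 0.18 to 0.2 without 1 library at a time; the cause was not tested.

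Of the named genes, calls were lost for 3 of 76 in D4_DUX against D4, for 1 of 52 in D4 against MEF and for 1 of 41 in iPSC against MEF. The 6 higher mesenchymal genes of D4_DUX against D4 were not followed over the alternatives and are outside these counts. In the first comparison 1 gene gained a call, Ddx3y, with an adjusted p from 0.0235 to 0.198. Adjusted p ran from 1.78e-05 to 0.0557 for Sox2, 0.0103 to 0.0996 for Ep300 and 0.00867 to 0.13 for Smarca4 in the first comparison, from 0.00342 to 0.0816 for Ep300 in the second and from 7.61e-07 to 0.0807 for Smarca4 in the third. Messages under 3 fragments, Duxf3 among them, cannot be compared.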

Other observations

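The tests of the label swap, of uncounted construct messages and of an 8-fold loss of pseudogenes, and the splits of the libraries, were chosen only after the results were seen, as were the genes and families named here. A cluster of Ly6 genes on chromosome 15 (74714839 to 75111970), which encode small surface and secreted proteins, held genes that were higher in the libraries labelled D4_DUX. Of 11 genes tested there 6 were higher and 1 lower than in D4, and 5 rose by at least 2-fold. The region was drawn after Ly6c1 and Slurp1 were seen at the top, so no test was made of it. Beside Ly6c1 and Slurp1 the 5 were Lypd2 (1.31), Ly6c2 (1.30) and Psca (1.01), and Ly6a, the Sca-1 antigen, was at 1040 ± 32.2 and 554 ± 36.5 FPKM in D4_DUX and D4. The Ly6c genes share sequence, so fragments can be divided between them. Canonical histone genes were higher in 27 of 41 cases and lower in 1, with a median log2 fold change of 0.49 (26 or 27 higher under each scaling). In D4 against MEF they were already higher in 31 cases against 1 lower. Because polyadenylated RNA was selected, changed polyadenylation of histone messages cannot be told apart from a changed amount. Ribosomal protein genes were lower in 24 of 84 cases and higher in 1, with a median of -0.13 (24 to 35 lower under the scalings).

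A set of 62 genes, 49 of them protein-coding, stood at least 8-fold higher in D4 than in both MEF and iPSC on the scale of log2(FPKM + 1). They included Msln and Upk3b of mesothelium, the keratin gene Krt14 of basal epithelium, Cd34 and Ly6a. In the libraries labelled D4_DUX 29 of the 62 were higher still and 12 lower. Of all 17114 genes tested 3432 were higher and 2634 lower. The 62 genes were not set against others of like abundance. Krt14 was at 49.6 ± 4.95 and 20.3 ± 1.81 FPKM in D4_DUX and D4, and Clec3b at 200 ± 12.3 and 71.1 ± 1.86 FPKM. Hbb-y, an embryonic globin, was at 29.2 ± 2.27 FPKM in D4 and listed at 0 in MEF and iPSC.

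Duxf3 was at or under the floor in the libraries labelled D4_DUX. A swap of the labels D4 and D4_DUX would place the messages of Dux targets in the D4 libraries, but Zscan4 fragments summed to 83.6 over the 3 libraries labelled D4_DUX and to 0 over the 3 D4 libraries, which argues against a swap. Messages of an introduced construct that the counting of the annotated gene does not take up may be present; with 0 Duxf3 fragments and no construct sequence among the files used here, this stays open. What raised the Zscan4 messages is untested.

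Macrophage markers were lower in D4_DUX than in D4. A smaller share of macrophages in the cultures labelled D4_DUX predicts that other macrophage genes fall as well: of 30 tested genes outside the fixed list (32 were listed before this test, after the fall of the fixed markers was seen) 28 were lower and 0 higher, with a median log2 fold change of -0.56, and among those with FPKM of at least 1 in D4 the median FPKM ratio was 0.246 over 15 genes (0.182 to 1.11) against 0.226 over 12 fixed markers (0.129 to 0.741), with Lyz2 the most abundant at 31 ± 1.23 and 149 ± 14.5 FPKM. The other genes were taken as mostly structural and signalling genes of these cells, which was not checked. On that reading, the median of -0.56 argues against less transcription of inflammatory genes alone in an unchanged share of macrophages. Less transcription of macrophage genes in general, in an unchanged share, would give the same fall and stays open. The labels name no sort that removes such cells, and FPKM of at least 1 was also reached in iPSC by 9 of the 16 markers and 17 of the 30 other genes. Whether Dux overexpression changed the number of macrophages or the cultures differed beforehand is untested and open.

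Among tested genes 23 had FPKM of at least 5 in every MEF and iPSC library and at least 8 times the FPKM of every day 4 library. They held 14 processed pseudogenes and 7 protein-coding genes, and the 65 genes that met the same limits the other way held 3 and 51. A strain or donor variant between the cultures, read through pseudogenes and local duplicates, stays open: the class was singled out from these genes, so its count of 14 does not test it. A processing difference that lowers every processed pseudogene in the day 4 libraries would need the class to fall, but the median log2 difference of all tested processed pseudogenes was -0.28 (quartiles -0.7 to 0.01), against -0.08 (-0.47 to 0.3) for protein-coding genes. This lies between the bounds of -1 and -0.25 set in advance, so a fall of the class stays open. A loss of the whole class of about 8-fold was set against the lower quartile of -0.7, with a bound chosen after the median was seen. Because 1 is added before the logarithm, pseudogenes of low FPKM would show such a loss only in part. The quartile therefore cannot decide on it. A biological difference between day 4 and the other groups remains among the open explanations, as untested.

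The 6 libraries of each comparison can be split in 10 ways, too few for a share under 0.05. In D4_DUX against D4 1 of the 10 splits, the real one, called 6066 genes and the highest other called 0. In D4 against MEF 1 of 10 called 10578 and the highest other 0, and in iPSC against MEF 1 of 10 called 14068 and the highest other 0. The rho across genes was 0.19 in the real split of the day 4 libraries, reached by 1 of 10, and 0.18 in the highest other. Each other split sets 2 libraries of a group with 1 of the other group. In the counts, the real difference then widens the spread within each side, so 0 is no measure of chance. For rho, such a split keeps part of the real difference, to whose size a rank correlation is blind. The 0.18 is therefore no measure of chance either.

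Xist, known from female cells, was at 17.3 to 29 FPKM and the Y-linked gene Ddx3y at 9.15 to 14.6 FPKM over the 12 libraries, although the labels name male embryos. Xist was at 26.4 ± 0.793 and 19.6 ± 1.44 FPKM in D4_DUX and D4 (log2 fold change 0.42, adjusted p = 0.000191) and Ddx3y at 11.7 ± 0.315 and 13.4 ± 1.11 FPKM (log2 fold change -0.18, adjusted p = 0.0529), while the Y-linked genes Eif2s3y, Kdm5d and Uty had log2 fold changes of 0.04, 0.06 and 0.00 (adjusted p = 0.513, 0.433 and 1). The iPSC libraries held the fibroblast genes Col1a1 and Postn at 184 ± 36.8 and 40.2 ± 9.67 FPKM.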
